A study of Rattus norvegicus with 15 samples.

How the data were processed

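RNA was sequenced from cultured rat cardiac stem cells (CSC, 3 cultures of 1 clone), beating cardiomyocyte colonies derived from such cells (iCM, 3 libraries), cardiomyocytes freshly isolated from neonatal hearts at postnatal day 1 to 2 (nCM, 3 libraries) and from adult hearts at 12 weeks (aCM, 3 libraries), all of the Wistar strain per the labels. Another 3 libraries came from 3 further CSC clones, 1 library per clone (cCSC1, cCSC2, cCSC3), and the first CSC library also served as clone 4. Per the labels' protocols, RNA was kept at an integrity number of at least 8, ribosomal RNA was removed with Ribo-Zero beads, and libraries were made from 1 µg of total RNA with a TruSeq kit using random primers.

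The authors deposited estimated counts per Ensembl rat gene, which need not be whole, for the 12 libraries of the 4 groups. The normalized columns beside them are log2 values as deposited by the authors, made from the counts by dividing by 1 factor per library and subtracting the median of each gene, as read from the values, and they were used here only for the authors' library factors. The submitters' processing notes name DESeq. The aligner, the counting program and the genome build are not given in the sources used here. The deposited table holds 26276 genes and 1 line without a gene name, which has a count of 0.0 in total and was left out. Symbols were taken from the table itself, and 5794 identifiers have none. None of its identifiers matched the reference gene table (0 matches), so no coordinates are given. Counting may or may not have used strand, so genes that overlap or share reads with a near-identical copy are uncertain, among them the globin genes and the pair Rrm2 and RRM2. The labels tie the 3 CSC libraries to separate cultures but do not say how the libraries of the other groups relate to animals or cultures, so p-values there measure the spread between these libraries, which may be technical. No pair of libraries within a group was as close as sampling noise allows. The lowest median chi-square per gene was 1.73, for iCM replicates 2 and 3, against 0.455 by chance, and each library counted as 1 replicate.

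The clone table, which like the first is titled as filtered on expression, holds 15979 genes. The authors deposited estimated counts there for cCSC3 and clone 4, and a signal on the scale of counts for cCSC1 and cCSC2, whose making is not given in the sources used here. The cCSC1 and cCSC2 values look like geometric means of 2 count columns. Under a tolerance of 0.001, 2.07% of the cCSC1 values below 100 were whole numbers, while 16.3% of their squares were whole under a tolerance of 0.005. For cCSC2 the shares were 1.23% and 13.6%, and for cCSC3 23.9% and 24.3%. The column of clone 4 equalled CSC replicate 1 for 15531 of 15531 matched genes within 1e-06. No count test was run on the clones.

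Estimated counts were rounded to whole numbers. Total counts were 35.4 M to 48.5 M in CSC, 44.2 M to 48.5 M in iCM, 35.8 M to 43.3 M in nCM and 20.7 M to 26.0 M in aCM, and the clone columns sum to 21.0 M, 25.0 M and 38.8 M. A count of 3 corresponds to between 0.0618 and 0.145 CPM (counts scaled to a common library total) in these libraries, which covers counting error only. Genes were kept by edgeR's filterByExpr with a minimum count of 10, which left 17242 genes and removed 9034, of which 6284 had no count in any of the 12 libraries. Libraries were scaled by TMM, and expression levels are given as TMM-scaled CPM, mean ± SD of 3 libraries. All 12 libraries entered 1 fit, and 6 contrasts were tested with edgeR's quasi-likelihood test and Benjamini-Hochberg adjustment over genes at 0.05. Log2 fold changes are given ± SE. Versions were R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

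Before the data were examined, 26 gene lists with 399 members were written down, and 373 members were found in the table. The list of mitochondrially encoded genes had no match and was not used, leaving 25 lists: sarcomere, calcium handling, ion channels and connexins, cardiac transcription factors, fetal-type and adult-type cardiac genes, fatty acid oxidation, nuclear-encoded respiratory chain, glycolysis, cell cycle, pluripotency, cardiac progenitor markers, Wnt signalling, TGF-beta and BMP signalling, fibroblast and matrix, endothelial, smooth muscle and pericyte, leukocyte, mast cell, erythroid, epicardial, skeletal muscle, neural and glial, adipogenic, and immediate early and heat shock. Some genes stand in more than 1 list. Robo4, Kcnip2, Ldha, Cd34 and Hspa1b each have 2 Ensembl identifiers in the table, and each tested identifier counts as 1 gene in the list counts. Lists were tested with limma's camera at a preset correlation of 0.01 between genes, adjusted over the lists. No list call held with an estimated correlation, in any of the 6 comparisons. The rule for named genes was also written beforehand. It takes the 6 genes with the largest fold up and down among passing genes with a symbol, non-overlapping ranges and a mean above the median, up to 4 passing members of each list with the largest change, the most highly expressed member that did not pass, and Kit. Which of these examples are printed was chosen after their values were seen.

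The test was checked on simulated counts with 200 changed genes. It recovered 92.4% to 100% of 4-fold changes, 56.7% to 79.1% of 2-fold changes and 13.4% to 31.3% of 1.5-fold changes over the 6 comparisons. Of its calls, 3.9% to 8.3% were false, with the highest share for iCM against nCM, above the 5% aimed at. In the data 31.4% to 78% of genes passed, far more than were changed here, so these shares need not hold for the reported calls. Alternatives were another scaling, other filters on low counts, DESeq2, fits of the compared groups only, a replicate block, a fold threshold, other list tests and leaving out each replicate. Chosen after seeing the data were the authors' own library factors, total count scaling, iCM replicate 1 alone, CSC replicate 3 alone, and prior counts of 0.5 and 10 for distances. Settings with 1 library in a group take the spread from the other groups, so their calls do not measure that group's own spread. Distances between libraries are root mean square differences of log2 CPM with a prior count of 2. Clone distances use log2(CPM + 1), with CPM from column totals, over 12187 genes with a mean CPM of at least 1.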

Results

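Transcript counts were available for 12 libraries in 4 groups of 3, with library totals of 20.7 M to 48.5 M counts. CSC are cultured cardiac stem cells, iCM are beating colonies differentiated from them, and nCM and aCM are cardiomyocytes isolated from neonatal and adult rat hearts. Of 17242 genes tested, 5412 to 13445 passed in the 6 pairwise comparisons. The gene Myh6, which encodes the alpha myosin heavy chain, took 5.18% to 7.34% of the counts of each aCM library.

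The first comparison asks what differs between iCM and CSC, the cell type they derive from. All 3 CSC libraries are cultures of 1 clone. The p-values use a spread per gene that is pooled over the 4 groups. To it the CSC libraries add spread between cultures of that clone, not between clones. Clones lay further apart than these cultures. The fibroblast and matrix list averaged 8.65 (log2) in cCSC2 against 6.42 to 6.94 in the cultures, but 6.57 in cCSC1 and 6.26 in cCSC3. With 1 library per clone, clone and library cannot be told apart, but a difference from CSC may depend on the clone. Heart muscle genes were far higher in iCM. The regulatory light chain gene Myl2 stood at 921 ± 93.2 CPM in iCM and 0.823 ± 0.867 in CSC (SD, n = 3 each; log2 fold change 10.04 ± 0.70). The CSC counts of Myl2 were 31, 81 and 0, and without CSC replicate 2 the log2 fold change was 11.15. Genes of endothelium, red blood cells and connective tissue rose with them, while cell cycle and glycolysis genes fell. In all, 6001 genes rose and 5373 fell. This balance depends on scaling, and was 5337 and 6197 with the authors' factors, 5408 and 6114 with RLE, and 6416 and 4744 with total counts.

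All 21 measured sarcomere genes rose (camera, adjusted p = 1.77e-10, and adjusted p = 0.148 with an estimated correlation). Tnni1, the slow skeletal troponin I of the fetal heart, rose by 9.64 ± 0.55 on the log2 scale, the cardiac actin Actc1 by 9.42 ± 0.78 and the beta myosin heavy chain gene Myh7 by 9.50 ± 0.78. The CSC counts of Tnni1 were 6, 41 and 2. Without CSC replicate 2 its value was 11.50, which rests on the counts of 6 and 2 and is no exact fold. Without that library Tbx20 gave 8.67, and without CSC replicate 1 Myh7 gave 10.12. Here and below, such a value is no exact fold where the CSC libraries left hold only a few counts. Of 14 calcium handling genes 11 rose and 2 fell (adjusted p = 0.000908, and adjusted p = 0.148 with an estimated correlation), led by phospholamban (Pln, 7.69 ± 0.31) and calsequestrin (Casq2, 6.03 ± 0.26). The calcium pump gene Atp2a2 did not pass (0.22 ± 0.20, adjusted p = 0.364). Among 17 cardiac transcription factors 15 rose and 1 fell (adjusted p = 3.83e-06, and adjusted p = 0.127 with an estimated correlation). Tbx20 rose by 7.94 ± 0.28 and the stress-responsive Ankrd1 by 8.93 ± 0.45, and Nkx2-5 stood at 7.09 ± 0.914 CPM against 0.0624 ± 0.0641, which is near the level of 3 counts. Of 19 ion channel and connexin genes 16 rose and 1 fell, 9 of 10 fetal-type cardiac genes rose, and 15 of 15 adult-type genes rose (adjusted p = 2.14e-05, 0.000104 and 7.95e-07, and adjusted p = 0.148, 0.148 and 0.189 with an estimated correlation).

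In metabolism, 18 of 25 fatty acid oxidation genes rose and 2 fell (adjusted p = 0.000343, and adjusted p = 0.271 with an estimated correlation). The fatty acid transporter Cd36 rose from 2.62 ± 2.45 CPM (1.20, 5.44 and 1.21 in the CSC libraries) to 1330 ± 150 CPM, and Acsl1 was level (log2 0.07 ± 0.14, adjusted p = 0.707). In the nuclear-encoded respiratory chain 10 of 25 genes rose, with Uqcrfs1 by 0.77 ± 0.15, and the list did not pass (adjusted p = 0.181). The number was 6 without CSC replicate 2, iCM replicate 1 or iCM replicate 3. The ATP synthase gene Atp5b, at 1950 ± 73.5 CPM in iCM, did not pass (0.41 ± 0.20, adjusted p = 0.0936), but it passed with total count scaling (0.51, adjusted p = 0.0251), the stricter low-count filter (0.49, adjusted p = 0.0295) and a fit of the 2 groups alone (0.38, adjusted p = 0.0165). Glycolysis genes fell, 15 of 17 against 1 that rose (adjusted p = 7.66e-06, and adjusted p = 0.217 with an estimated correlation). Pyruvate kinase (Pkm) changed by -2.91 ± 0.19 and the glucose transporter Slc2a1 by -2.82 ± 0.18, while the muscle enolase Eno3 did not pass (0.10 ± 0.51, adjusted p = 0.878) except without CSC replicate 2 (1.44, adjusted p = 0.000195) and with CSC replicate 3 alone (1.41, adjusted p = 0.00257). All 27 cell cycle genes fell (adjusted p = 1.04e-08, and adjusted p = 0.217 with an estimated correlation), Rrm2 by -2.78 ± 0.21 and the mitotic cyclin Ccnb1 by -2.10 ± 0.18.

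Markers of other heart cell types stood higher in iCM beside the cardiomyocyte genes. All 15 endothelial genes rose, with the endothelial cadherin Cdh5 by 8.89 ± 0.38 and Pecam1 by 8.62 ± 0.52, and 6 of 7 erythroid genes rose. Hba2, an alpha globin, was at 9280 ± 702 CPM in iCM and at 0.0479, 47.7 and 0.0887 CPM in the 3 CSC libraries. Its log2 fold change of 9.18 rests on CSC replicate 2, and without that library the CSC counts are 2 and 3, too few for a fold (adjusted p = 2.69e-09). The exception was Ahsp, a globin chaperone, which was lower in iCM by 1.14 on the log2 scale and no longer passed without CSC replicate 2 (-0.94, adjusted p = 0.0579), CSC replicate 3 (-0.87, adjusted p = 0.0694), iCM replicate 2 (-1.09, adjusted p = 0.0556) or iCM replicate 3 (-1.11, adjusted p = 0.0528), or with iCM replicate 1 alone (-0.99, adjusted p = 0.209). Of 14 leukocyte genes 13 rose, with the lysozyme Lyz2 by 7.51 ± 0.42, and Cd14 did not pass (-0.05 ± 0.23, adjusted p = 0.862). Among fibroblast and matrix genes 14 of 18 rose and 2 fell, with the proteoglycan Dcn by 9.02 ± 0.65 and periostin (Postn) by 8.61 ± 0.54. Without CSC replicate 2 the log2 values were 9.67 for Cdh5, 9.95 for Pecam1, 8.68 for Lyz2, 10.94 for Dcn and 9.56 for Postn. Fibronectin (Fn1) was at 4820 ± 59.7 CPM in iCM and 3920 ± 2220 in CSC and did not pass (adjusted p = 0.508). With CSC replicate 3 alone its log2 value was 1.82. Smooth muscle and pericyte genes rose in 10 of 11 with 1 that fell, led by Mcam (8.15 ± 0.23), epicardial genes in 8 of 9, among them Wt1 (5.77 ± 0.16), and mast cell genes in 5 of 6, led by the protease Cpa3 (3.73 ± 0.36). These 7 lists had adjusted p between 5.64e-08 and 0.0217, and adjusted p between 0.127 and 0.319 with an estimated correlation.

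All 14 immediate early and heat shock genes rose (adjusted p = 1.56e-07, and adjusted p = 0.148 with an estimated correlation), with Fos at 1950 ± 104 CPM against 3.27 ± 3.36 (1.36, 7.15 and 1.30 in the CSC libraries). Of 11 skeletal muscle genes 10 rose (adjusted p = 0.0375, and adjusted p = 0.486 with an estimated correlation), but 4 passed with iCM replicate 1 alone. The embryonic myosin Myh3 was at 2.38, 584 and 682 CPM in the 3 iCM libraries. Cardiac progenitor markers rose in 13 of 16 with 1 that fell (adjusted p = 6.55e-05, and adjusted p = 0.127 with an estimated correlation), among them the receptor Kdr (7.73 ± 0.30) and Cd34 (ENSRNOG00000050078, 9.39 ± 0.42, and 10.52 without CSC replicate 2). Pluripotency genes (5 of 10 rose), Wnt signalling (7 rose and 5 fell of 17), TGF-beta and BMP signalling (9 of 18 rose), neural and glial genes (7 rose and 1 fell of 9) and adipogenic genes (6 rose and 1 fell of 7) did not pass as lists (adjusted p = 0.178, 0.392, 0.0749, 0.149 and 0.0836). Klf4 rose by 1.27 ± 0.17, Myc was level (adjusted p = 0.989), and the fat hormone gene Adipoq rose by 6.03 ± 0.37. Among the genes picked by the rule for named genes were Myl9, elastin (Eln) and the carboxylesterase Ces1d, up by 9.93, 9.90 and 9.77, and the cystine transporter Slc7a11, aggrecan (Acan) and Aldh3a1, at -6.19, -5.38 and -5.23. Myl9 and Eln gave 11.24 and 11.89 without CSC replicate 2, and Acan -4.65 without CSC replicate 3. Adjusted over the list alone, counts were identical except for 7 respiratory chain genes and 17 ion channel and connexin genes that rose.

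**Figure D1:**
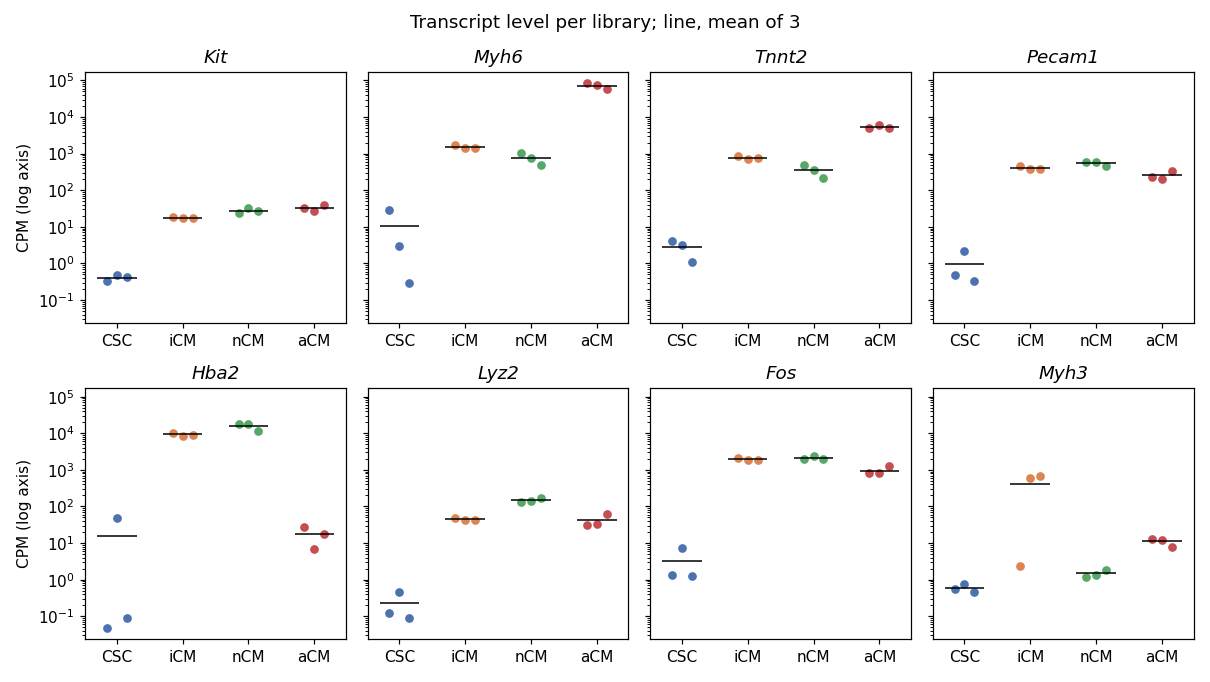
Transcript levels of 8 genes in each of the 12 libraries, in TMM-scaled CPM on a log axis, with points for libraries and lines for the mean of 3. Kit lies between 0.335 and 0.469 CPM in CSC and between 17.3 and 40.4 CPM in the other groups, and Myh3 is high in iCM replicates 2 and 3 but not in iCM replicate 1 (2.38, 584 and 682 CPM).

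Kit, the receptor tyrosine kinase named in the study's title, had few transcripts in CSC. Its level was 0.406 ± 0.0676 CPM in CSC, 18.0 ± 1.01 in iCM, 27.8 ± 4.05 in nCM and 33.4 ± 6.87 in aCM (SD, n = 3 each). The CSC values rest on rounded counts of 14, 22 and 14, above the level of 3 counts (0.0619 to 0.0847 CPM). Kit was higher than in CSC by 5.45 ± 0.21 in iCM, 6.08 ± 0.22 in nCM and 6.34 ± 0.22 in aCM (log2, adjusted p = 1.42e-10, 5.05e-11 and 1.98e-11). It was lower in iCM than in nCM (-0.63 ± 0.15, adjusted p = 0.00818) and in aCM (-0.89 ± 0.16, adjusted p = 0.000234), and aCM and nCM did not differ detectably (0.26 ± 0.15, adjusted p = 0.159). The difference between iCM and nCM did not pass with iCM replicate 1 alone (-0.53, adjusted p = 0.26). In the clones, Kit was at 0.399 CPM in cCSC1, 0.517 in cCSC2 and 0.345 in cCSC3.

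The comparison of iCM with nCM asks how far the derived cells match cardiomyocytes of the newborn heart. Differences were smaller here. Several contractile and metabolic genes were moderately higher in iCM, such as the Z-disc protein Csrp3 at 83.9 ± 1.69 against 33.1 ± 5.05 CPM (SD, n = 3 each). Leukocyte genes were lower in iCM, and skeletal muscle genes were higher in 2 of the 3 iCM libraries, replicates 2 and 3. The median iCM to nCM ratio was 1.92 over sarcomere genes and 1.05 over fibroblast and matrix genes. It was 0.346 over leukocyte, 0.581 over erythroid and 0.730 over endothelial genes. Cell makeup and the state of the cardiomyocytes therefore cannot be told apart in the differences below. In all 3147 genes rose and 2265 fell, against 2658 and 2674 with total count scaling, and 1866 passed with at least a 2-fold change. The count of 5412 was 3494 without iCM replicate 2 and 3570 without iCM replicate 3. It was lower still with iCM replicate 1 alone, a setting that takes the spread from the other groups. There Myh3 gave a log2 value of 0.70 in place of 8.16, while Lyz2 gave -1.62 in place of -1.73.

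Of 21 sarcomere genes 12 rose, 15 adjusted over the list alone (camera, adjusted p = 0.000343, and adjusted p = 0.62 with an estimated correlation). Without iCM replicate 1, 2 or 3 the number was 7, 7 and 6, and without nCM replicate 2 or 3 it was 6 and 7. Csrp3 rose by 1.34 ± 0.11 and alpha-actinin (Actn2) by 1.19 ± 0.17. Myh6 was at 1540 ± 173 against 749 ± 268 CPM and did not pass (adjusted p = 0.394), but it passed in a fit of these 2 groups alone (1.02, adjusted p = 0.0102). Of 14 calcium handling genes 11 rose (adjusted p = 0.000325, and adjusted p = 0.369 with an estimated correlation), 7 without iCM replicate 2 and 6 without iCM replicate 3 or nCM replicate 2. The junction protein Jph2 rose by 1.68 ± 0.19 and Casq2 by 1.22 ± 0.20, and the release channel Ryr2 did not pass (0.61 ± 0.51, adjusted p = 0.381, and adjusted p = 0.0101 in a fit of the 2 groups alone). Of 15 adult-type genes 7 rose and 1 fell, 9 and 1 adjusted over the list alone (adjusted p = 0.0172, and adjusted p = 0.675 with an estimated correlation). The insulin-responsive glucose transporter Slc2a4 rose by 3.16 ± 0.18, and the potassium channel Kcnj2 changed by -1.32 ± 0.22. Fetal-type genes rose in 5 of 10, 6 adjusted over the list alone (adjusted p = 0.0415, and adjusted p = 0.62 with an estimated correlation), and 3 passed without iCM replicate 2 or 3 and 2 without nCM replicate 2. Ion channels and connexins (6 rose and 3 fell of 19, 7 and 4 adjusted over the list alone, with Kcnh2 up by 1.19 ± 0.15) and cardiac transcription factors (8 rose and 2 fell of 17, 9 and 2 adjusted over the list alone) did not pass as lists (adjusted p = 0.392 and 0.124). Of the ion channels and connexins, 3 rose without iCM replicate 1 or nCM replicate 3, and 2 without iCM replicate 3 or nCM replicate 2. Of the cardiac transcription factors, 0 fell without iCM replicate 2 or 3 or nCM replicate 2. In that list 1 fell without iCM replicate 1 or nCM replicate 1 or 3. Ankrd1 rose by 1.59 ± 0.31, and Gata4 did not differ detectably (0.10 ± 0.16, adjusted p = 0.659).

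Fatty acid oxidation genes rose in 14 of 25, 16 adjusted over the list alone, with the carnitine transferase Cpt1b by 1.23 ± 0.24, and 9 rose without nCM replicate 2. Respiratory chain genes rose in 7 of 25, with Sdha by 0.73 ± 0.17, while Atp5b did not pass (adjusted p = 0.0604) except with DESeq2 (0.51, adjusted p = 0.0216) and without nCM replicate 1 (0.70, adjusted p = 0.0316). Glycolysis genes rose in 7 of 17, 9 adjusted over the list alone, with Aldoa by 0.84 ± 0.20 and Pkm by 0.82 ± 0.18. These lists passed (adjusted p = 0.000222, 0.0019 and 0.00145, and adjusted p = 0.62, 0.763 and 0.62 with an estimated correlation). With fry the respiratory chain did not pass (adjusted p = 0.109). Glycolysis counted 4, 3 and 3 genes without iCM replicate 1, 2 or 3, and 3 without nCM replicate 2 or 3. Respiratory chain genes counted 4 without iCM replicate 1 or 3 or nCM replicate 2, and 12 without nCM replicate 1. Without nCM replicate 3, whose respiratory chain genes were the lowest, 4 rose and the list median was 0.13 in place of 0.33. Of 27 cell cycle genes 5 fell, 1 adjusted over the list alone (adjusted p = 0.0373, and adjusted p = 0.882 with an estimated correlation), and with fry the list did not pass (adjusted p = 0.357). Without any 1 of the iCM replicates, or nCM replicate 1 or 2, 1 fell, and 3 fell without nCM replicate 3. Ccnb2 changed by -0.49 ± 0.12, and the proliferation marker Mki67 did not pass (-0.40 ± 0.21, adjusted p = 0.169, and adjusted p = 0.02 in a fit of the 2 groups alone).

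Of 14 leukocyte genes 13 fell and 1 rose (adjusted p = 7e-07, and adjusted p = 0.62 with an estimated correlation), with Lyz2 at -1.73 ± 0.27, the macrophage receptor Csf1r at -1.72 ± 0.29 and Aif1 at -2.05 ± 0.26, and 5 fell with iCM replicate 1 alone. With that library alone, neither Lyz2 (-1.62, adjusted p = 0.0682) nor Csf1r (-1.60, adjusted p = 0.0732) passed, though their folds stayed close. Of 15 endothelial genes 6 fell (adjusted p = 0.00884, and adjusted p = 0.62 with an estimated correlation), and 3 fell without iCM replicate 2 or nCM replicate 2. With fry this list did not pass (adjusted p = 0.0639). Emcn changed by -1.32 ± 0.35 but did not pass without iCM replicate 2 (-1.26, adjusted p = 0.0553) or with DESeq2 (-1.34, adjusted p = 0.0769), and Cldn5 changed by -1.24 ± 0.30 but did not pass without nCM replicate 2 (-0.89, adjusted p = 0.0534). Pecam1 did not pass (-0.45 ± 0.36, adjusted p = 0.356, and adjusted p = 0.0215 in a fit of the 2 groups alone). Of 7 erythroid genes 2 fell, 3 adjusted over the list alone (list adjusted p = 0.0917), and 1 fell without replicate 2 or 3 of iCM or of nCM. Epb42, a red cell membrane protein, changed by -0.85 ± 0.16, and Hba2 was at 9280 ± 702 against 16100 ± 3610 CPM (adjusted p = 0.659, and adjusted p = 0.0124 in a fit of the 2 groups alone).

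Skeletal muscle genes rose in 8 of 11, 9 adjusted over the list alone (adjusted p = 0.00671, and adjusted p = 0.62 with an estimated correlation). With iCM replicate 1 alone, 1 rose and the list median was -0.03 in place of 4.53. The myogenic regulator Myog was at 0.298, 45.6 and 52.0 CPM in the 3 iCM libraries and Myh3 at 2.38, 584 and 682. Adipogenic genes rose in 4 of 7, 5 adjusted over the list alone (adjusted p = 0.0134, and adjusted p = 0.62 with an estimated correlation), and 4 rose with iCM replicate 1 alone. Adipoq rose by 5.05 ± 0.34 and the fat cell regulator Cebpa by 2.68 ± 0.32, and Fabp4 did not pass (-0.73 ± 0.38, adjusted p = 0.166, and adjusted p = 0.03 in a fit of the 2 groups alone). Of 16 progenitor markers 5 rose and 5 fell, 6 and 6 adjusted over the list alone (list adjusted p = 0.959), with the growth factor receptor Met up by 2.97 ± 0.19 and Thy1 up by 3.41 ± 0.76, but at 0.69 with iCM replicate 1 alone (adjusted p = 0.626). Of these markers 3 rose and 2 fell without nCM replicate 2, and 4 rose and 3 fell without iCM replicate 2. Immediate early and heat shock genes had 1 member that fell, 0 adjusted over the list alone, and a median that changed sign across 4 scalings (-0.04 to 0.03). That gene, Atf3, changed by -0.93 ± 0.31 and did not pass with the replicate block, with iCM replicate 1 alone, or without any 1 of the iCM replicates, nCM replicate 1 or nCM replicate 2 (log2 -0.97 to -0.76, adjusted p of 0.0629 to 0.399). Fos was at 1950 ± 104 and 2150 ± 262 CPM (adjusted p = 0.842). The other 8 lists did not pass, with adjusted p of 0.18 to 0.959. Among the genes picked by the rule for named genes, the carboxylesterase Ces1d was high in iCM (1360 ± 194 against 0.201 ± 0.174 CPM). So were the detoxification enzymes Gsta1 (log2 6.81) and Akr1b8 (6.48) and the matrix protein Spp1 (1520 ± 335 against 23.7 ± 13.2 CPM). Spp1 and Akr1b8 were higher still in CSC, at 8150 ± 1780 and 799 ± 277 CPM. Those picked as lower included Iqce (-1.91) and the leukocyte integrin Itgal (-1.81), and Iqce did not pass with iCM replicate 1 alone (-1.99, adjusted p = 0.119) and was at -1.25 without nCM replicate 3.

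The comparison of iCM with aCM asks how the derived cells stand against the mature heart. Adult contractile, calcium and mitochondrial genes were much lower in iCM. The M-band gene Myom2 was at 27.7 ± 4.97 CPM in iCM and 5090 ± 424 in aCM (SD, n = 3 each), and the fetal troponin Tnni1 at 315 ± 24.8 against 0.947 ± 0.554. Cell cycle, matrix and globin genes were higher in iCM. Fibroblast and matrix genes summed to 33630 to 35790 CPM in iCM libraries and 5196 to 9215 in aCM libraries. Sarcomere genes summed to 10620 to 11890 against 106100 to 136300, and smooth muscle and pericyte genes to 1652 to 2136 against 2896 to 3581. Cell makeup and the state of the cardiomyocytes therefore cannot be told apart in the differences below. In all 5698 genes rose and 5190 fell, so that 52.3% of passing genes rose, against 66.2% with total count scaling.

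Of 21 sarcomere genes 19 fell and 2 rose (camera, adjusted p = 1.88e-05, and adjusted p = 0.374 with an estimated correlation). Myom2 changed by -7.52 ± 0.50 and Myh6 by -5.55 ± 1.06, and those that rose were Tnni1 (8.33 ± 0.52, and 8.96 without aCM replicate 2) and the atrial light chain Myl4 (1.25). Myl4 did not pass without aCM replicate 2 (1.01, adjusted p = 0.0552) or with iCM replicate 1 alone (0.90, adjusted p = 0.206). Of 14 calcium handling genes 13 fell and 1 rose (adjusted p = 1.18e-06, and adjusted p = 0.119 with an estimated correlation), led by Hrc at -7.69 ± 0.32, Ryr2 at -6.56 ± 0.64 and Atp2a2 at -5.48 ± 0.25. Of 19 ion channel and connexin genes 16 fell (adjusted p = 9.56e-09, and adjusted p = 0.191 with an estimated correlation), with the potassium channel Kcnd2 at -7.07 ± 0.35. Cacna1h did not pass (adjusted p = 0.204, and adjusted p = 0.0404 in a fit of the 2 groups alone). All 15 adult-type genes fell (adjusted p = 1.13e-06, and adjusted p = 0.374 with an estimated correlation), with the mitochondrial creatine kinase Ckmt2 at -8.36 ± 0.63 and Slc2a4 at -4.62 ± 0.19. Fetal-type genes were split, 4 up and 4 down of 10 (list adjusted p = 0.725), with the growth factor Igf2 up by 6.01 ± 0.92.

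Fatty acid oxidation genes fell in 24 of 25 (adjusted p = 1.59e-12, and adjusted p = 0.194 with an estimated correlation), with lipoprotein lipase (Lpl) at -5.03 ± 0.31 and Acadl at -3.83 ± 0.15. Cd36 did not pass (-0.53 ± 0.41, adjusted p = 0.281, and adjusted p = 0.00396 in a fit of the 2 groups alone). All 25 respiratory chain genes fell (adjusted p = 1.59e-12, and adjusted p = 0.374 with an estimated correlation), with Ndufs1 at -3.13 ± 0.18 and Sdha at -2.61 ± 0.18. Glycolysis genes fell in 11 of 17 and rose in 2, 3 adjusted over the list alone (adjusted p = 0.0311, and adjusted p = 0.624 with an estimated correlation). Without any 1 of the iCM replicates, or without aCM replicate 1 or 2, 1 rose. All 27 cell cycle genes rose (adjusted p = 5.12e-13, and adjusted p = 0.346 with an estimated correlation), with Rrm2 by 4.97 ± 0.25 and the mitotic kinase Cdk1 by 4.85 ± 0.24.

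Fibroblast and matrix genes rose in 14 of 18 (adjusted p = 1.88e-05, and adjusted p = 0.374 with an estimated correlation), with Postn by 6.56 ± 0.49 and Fn1 by 4.94 ± 0.45, and Dcn did not pass (adjusted p = 0.354). TGF-beta and BMP genes rose in 13 of 18, with 1 that fell adjusted over the list alone (adjusted p = 0.0031, and adjusted p = 0.534 with an estimated correlation). All 7 erythroid genes rose (adjusted p = 0.000903, and adjusted p = 0.239 with an estimated correlation), with Hba2 by 9.07 ± 1.76. Leukocyte genes fell in 5 of 14 and rose in 1 (list adjusted p = 0.477, median -0.23 to 0.05 over 4 scalings), and 3 fell without iCM replicate 3 and 2 without aCM replicate 3. Among them the antigen-presentation chain Cd74 changed by -4.14 ± 0.26 and Cd14 rose by 2.66 ± 0.26, and Lyz2 did not pass (0.11 ± 0.27, adjusted p = 0.746). Endothelial genes rose in 4 of 15 and fell in 1, 3 and 1 adjusted over the list alone (list adjusted p = 0.557), and 2 rose without aCM replicate 1 or 2. Pecam1 did not pass (0.67 ± 0.36, adjusted p = 0.121, adjusted p = 0.0104 in a fit of the 2 groups alone, and adjusted p = 0.03 with total count scaling). Skeletal muscle genes rose in 7 of 11 and fell in 1 (list adjusted p = 0.477). That list averaged 0.039 (log2 CPM) in iCM replicate 1, below every aCM library (0.708 to 0.981). It lay above all aCM libraries in iCM replicates 2 and 3, with 4.257 in replicate 3. The higher list average in iCM therefore rests on replicates 2 and 3. The other 10 lists did not pass, with adjusted p of 0.125 to 0.945. Among the genes picked by the rule for named genes, Cmya5, Acss1 and Xirp2 were low in iCM beside Myom2 and Ryr2 (log2 -7.32, -6.55 and -5.92), and the lipoxygenase Alox15 was high beside the globins (7.36).

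The comparison of aCM with nCM sets adult beside newborn cardiomyocyte isolates, whose cell makeup may differ as well. Erythroid genes summed to 23650 to 35620 CPM in nCM libraries and 80.2 to 100 in aCM libraries. Fibroblast and matrix genes summed to 29100 to 35680 against 5196 to 9215, and sarcomere genes to 4097 to 7720 against 106100 to 136300. Age and cell makeup therefore cannot be told apart in the differences below. The aCM libraries had more transcripts of adult contractile genes, with Myh6 at 71800 ± 12100 CPM against 749 ± 268 in nCM (SD, n = 3 each). Fatty acid and respiratory chain genes were higher in aCM, and cell cycle, matrix and globin genes were lower. In all 5316 genes rose and 5499 fell, so that 49.2% of passing genes rose, against 33.6% with total count scaling.

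Of 21 sarcomere genes 19 rose and 1 fell (camera, adjusted p = 1.09e-06, and adjusted p = 0.323 with an estimated correlation). Myom2 rose by 7.51 ± 0.50 and Myh6 by 6.58 ± 1.12, Tnni1 changed by -7.38 ± 0.51 (-8.01 without aCM replicate 2), and Myl4 did not pass (-0.03 ± 0.39, adjusted p = 0.95). Calcium handling genes rose in 13 of 14 with 1 that fell (adjusted p = 3.2e-07, and adjusted p = 0.0905 with an estimated correlation), with Hrc by 7.88 ± 0.33, Ryr2 by 7.16 ± 0.66 and Atp2a2 by 6.16 ± 0.25. Ion channels and connexins rose in 17 of 19 (adjusted p = 3.11e-08, and adjusted p = 0.179 with an estimated correlation), with the potassium channel Kcnj3 by 5.91 ± 0.24. All 15 adult-type genes rose (adjusted p = 3.2e-07, and adjusted p = 0.323 with an estimated correlation), with Ckmt2 by 10.60 ± 0.70 and Slc2a4 by 7.78 ± 0.22. Fatty acid oxidation genes rose in 24 of 25 and respiratory chain genes in 25 of 25 (adjusted p = 7.29e-13 and 1e-12, and adjusted p = 0.179 and 0.34 with an estimated correlation), with Cpt1b up by 4.78 ± 0.28 and Ndufs1 by 3.82 ± 0.19. Cd36 did not pass (0.11 ± 0.41, adjusted p = 0.833).

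Cell cycle genes fell in 26 of 27 (adjusted p = 3.35e-13, and adjusted p = 0.323 with an estimated correlation), with Cdk1 at -5.42 ± 0.24 and Birc5 at -5.10 ± 0.25. Aurka did not pass (-0.11 ± 0.16, adjusted p = 0.592) except with total count scaling (-0.45, adjusted p = 0.0186). Fibroblast and matrix genes fell in 16 of 18 (adjusted p = 8.16e-06, and adjusted p = 0.34 with an estimated correlation), with Postn at -7.49 ± 0.51 and Fn1 at -3.69 ± 0.42. Igf2 changed by -6.31 ± 0.93. All 7 erythroid genes fell (adjusted p = 0.000422, and adjusted p = 0.194 with an estimated correlation), with Hba2 at -9.86 ± 1.82. Leukocyte genes fell in 13 of 14 and rose in 1 (adjusted p = 0.00914, and adjusted p = 0.458 with an estimated correlation), with Lyz2 at -1.83 ± 0.28 and Cd74 up by 2.73 ± 0.24, and 8 fell without nCM replicate 3. The lipid droplet gene Plin4 (7.38) and Cmya5 (7.24) were among the rises picked by the rule for named genes, and Alox15 (-8.82) among the falls beside the globins. Cardiac transcription factors rose in 9 of 17 and fell in 1, and glycolysis genes rose in 11 of 17 (adjusted p = 0.0287 and 0.000672, and adjusted p = 0.383 and 0.458 with an estimated correlation). TGF-beta and BMP genes fell in 13 of 18 and rose in 2, 14 and 2 adjusted over the list alone, and endothelial genes fell in 10 of 15 (adjusted p = 0.0105 and 0.0407, and adjusted p = 0.458 and 0.578 with an estimated correlation). The other 11 lists did not pass, with adjusted p of 0.126 to 0.833.

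The comparison of nCM with CSC gives the newborn counterpart of the first one. Heart muscle, endothelial, matrix and globin genes were higher in nCM, with the myosin light chain Myl2 at 455 ± 159 CPM against 0.823 ± 0.867 (SD, n = 3 each). The secreted protein gene Spp1 and the keratin gene Krt8 were much lower, at 23.7 ± 13.2 against 8150 ± 1780 CPM and 6.31 ± 1.76 against 1660 ± 294. In all 6324 genes rose and 6112 fell. This balance too depends on scaling, and was 5669 and 6782 with the authors' factors and 7127 and 5301 with total counts. All 21 sarcomere genes rose (camera, adjusted p = 9.2e-09, and adjusted p = 0.19 with an estimated correlation), with Myl2 by 9.02 ± 0.67 and Myh7 by 8.59 ± 0.76. Calcium handling genes rose in 9 of 14 and fell in 3, 4 adjusted over the list alone (adjusted p = 0.0497, and adjusted p = 0.248 with an estimated correlation). Pln rose by 6.84 ± 0.30, and Atp2a2, at 382 ± 22.6 against 525 ± 59.9 CPM, did not pass (adjusted p = 0.0592), but it passed with RLE scaling, the authors' factors, no low-count filter, a fit of the 2 groups alone, DESeq2, and without CSC replicate 1 (adjusted p of 2.19e-05 to 0.039). Cardiac transcription factors rose in 16 of 17 with 1 that fell (adjusted p = 2.85e-05, and adjusted p = 0.19 with an estimated correlation), with Tbx20 by 8.53 ± 0.28. All 15 endothelial genes rose (adjusted p = 1.36e-07, and adjusted p = 0.19 with an estimated correlation), with Cdh5 by 9.37 ± 0.39 and Pecam1 by 9.07 ± 0.53. Leukocyte genes rose in 13 of 14 with 1 that fell and erythroid genes in 6 of 7 (adjusted p = 3.41e-06 and 0.00259, and adjusted p = 0.19 and 0.19 with an estimated correlation), with Lyz2 by 9.24 ± 0.43. Hba2 rose by 9.97 ± 1.82, a value that rests on CSC replicate 2, as the other CSC libraries hold 2 and 3 counts of it (adjusted p = 1.66e-09 without that library). Ahsp did not pass (-0.09 ± 0.38, adjusted p = 0.837). Fibroblast and matrix genes rose in 10 of 18 and fell in 3 (adjusted p = 0.0106, and adjusted p = 0.48 with an estimated correlation), with Dcn by 10.01 ± 0.67 and Postn by 9.54 ± 0.56. All 14 immediate early and heat shock genes rose (adjusted p = 8.42e-07, and adjusted p = 0.19 with an estimated correlation), with Fos by 9.33 ± 0.65. Without CSC replicate 2 the log2 values were 10.13 for Myl2, 9.26 for Tbx20, 10.15 for Cdh5, 10.40 for Pecam1, 10.40 for Lyz2, 11.92 for Dcn, 10.48 for Postn and 10.64 for Fos, and without CSC replicate 1 that of Myh7 was 9.20. Cell cycle genes fell in 25 of 27 and glycolysis genes in 15 of 17 with 1 that rose (adjusted p = 3.41e-06 and 5.58e-06, and adjusted p = 0.31 and 0.238 with an estimated correlation). Rrm2 changed by -2.93 ± 0.21 and Pkm by -3.73 ± 0.20, and Pcna did not pass (adjusted p = 0.344). Respiratory chain genes were split, 2 up and 3 down of 25, 0 up and 1 down adjusted over the list alone, with a median of -0.16 to 0.14 over 4 scalings, and Ndufs1 changed by -0.73 ± 0.17. In that list 6 rose without nCM replicate 3, and 5 fell without nCM replicate 1. Of 11 skeletal muscle genes 1 rose, 0 adjusted over the list alone, namely the fast light chain Mylpf (2.78 ± 0.86), which did not pass with CSC replicate 3 alone (2.36, adjusted p = 0.169). Myh3 did not pass (adjusted p = 0.451, and adjusted p = 0.00362 in a fit of the 2 groups alone). Ion channels and connexins rose in 16 of 19 and fell in 2, fetal-type genes rose in 9 of 10 and fell in 1, and adult-type genes rose in 13 of 15 (adjusted p = 0.000142, 0.000898 and 1.86e-05, and adjusted p = 0.19, 0.19 and 0.238 with an estimated correlation). Progenitor markers rose in 11 of 16 and fell in 2, smooth muscle and pericyte genes rose in 10 of 11 and fell in 1, mast cell genes rose in 6 of 6 and epicardial genes in 8 of 9 (adjusted p = 0.00258, 0.000123, 0.0138 and 0.00119, and adjusted p = 0.19, 0.19, 0.238 and 0.238 with an estimated correlation). In all 8 lists did not pass, with adjusted p of 0.0819 to 0.851.

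The comparison of aCM with CSC gave the largest number of passing genes, with 7449 up and 5996 down. The split was 6540 and 6723 with the authors' factors and 6619 and 6570 with total counts. The median over all genes was 0.287 on the log2 scale. Adult muscle genes showed large folds, with Myh6 at 71800 ± 12100 CPM against 10.7 ± 15.7 and myoglobin (Mb) at 8590 ± 374 against 1.55 ± 1.71 (SD, n = 3 each). Sarcomere genes rose in 20 of 21 (camera, adjusted p = 1e-08, and adjusted p = 0.215 with an estimated correlation), with Myom2 by 12.00 ± 0.61. Tnni1 did not pass (1.32 ± 0.67, adjusted p = 0.0883, 3.16 with adjusted p = 0.00069 without CSC replicate 2, 3.94 with adjusted p = 0.00429 with CSC replicate 3 alone, and 0.70 with adjusted p = 0.456 without aCM replicate 2). Calcium handling genes rose in 13 of 14 with 1 that fell (adjusted p = 3.44e-05, and adjusted p = 0.148 with an estimated correlation), with Ryr2 by 11.98 ± 0.80 and Casq2 by 10.53 ± 0.30. Without CSC replicate 1 the log2 values of Myom2 and Ryr2 were 13.13 and 13.53, and the CSC libraries held Myh6 at 28.8, 2.97 and 0.296 CPM and Mb at 3.47, 1.00 and 0.177. All 25 fatty acid oxidation and all 25 respiratory chain genes rose (adjusted p = 5.39e-09 and 1.85e-07, and adjusted p = 0.215 and 0.348 with an estimated correlation), with Lpl by 11.11 ± 0.41 and Sdha by 3.13 ± 0.18. Glycolysis genes fell in 11 of 17 and rose in 3 (adjusted p = 0.03, and adjusted p = 0.602 with an estimated correlation), with the enolase Eno1 at -2.92 ± 0.20 and the muscle phosphofructokinase Pfkm up by 5.08 ± 0.25. All 27 cell cycle genes fell (adjusted p = 8.12e-13, and adjusted p = 0.241 with an estimated correlation), with Rrm2 at -7.75 ± 0.27 and Cdk1 at -6.44 ± 0.25. All 15 endothelial genes rose (adjusted p = 8.43e-06, and adjusted p = 0.241 with an estimated correlation), with Cdh5 by 8.41 ± 0.38 (9.19 without CSC replicate 2). Fibroblast and matrix genes went both ways, 7 up and 9 down of 18 (list adjusted p = 0.486), with Fn1 at -4.65 ± 0.44. Erythroid genes rose in 3 of 7 and fell in 1 (list adjusted p = 0.46), and that gene was Ahsp, with counts of 9, 0 and 2 in aCM (0.192 ± 0.243 against 54.9 ± 29.2 CPM). Without CSC replicate 2, 5 erythroid genes rose. Hba2 did not pass (0.11 ± 1.27, adjusted p = 0.943), but it passed without CSC replicate 2 (adjusted p = 6.28e-07), the library that held 47.7 CPM of it, and with CSC replicate 3 alone (adjusted p = 3.7e-05). No fold is given for these, as the other 2 CSC libraries hold 2 and 3 counts. Ion channels and connexins rose in 18 of 19, cardiac transcription factors in 16 of 17 with 1 that fell, fetal-type genes in 8 of 10 and adult-type genes in 15 of 15 (adjusted p = 3.16e-07, 7.18e-05, 0.0021 and 8.54e-07, and adjusted p = 0.166, 0.166, 0.241 and 0.241 with an estimated correlation). Progenitor markers rose in 11 of 16 and fell in 4, smooth muscle and pericyte genes rose in 10 of 11, and leukocyte genes rose in 13 of 14 and fell in 1 (adjusted p = 0.0385, 0.000188 and 0.000205, and adjusted p = 0.27, 0.148 and 0.27 with an estimated correlation). Mast cell genes rose in 6 of 6, epicardial genes in 8 of 9 with 1 that fell, and immediate early and heat shock genes in 14 of 14 (adjusted p = 0.0178, 0.00843 and 3.44e-05, and adjusted p = 0.252, 0.345 and 0.252 with an estimated correlation). In all 8 lists did not pass, with adjusted p of 0.336 to 0.916.

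**Figure D2:**
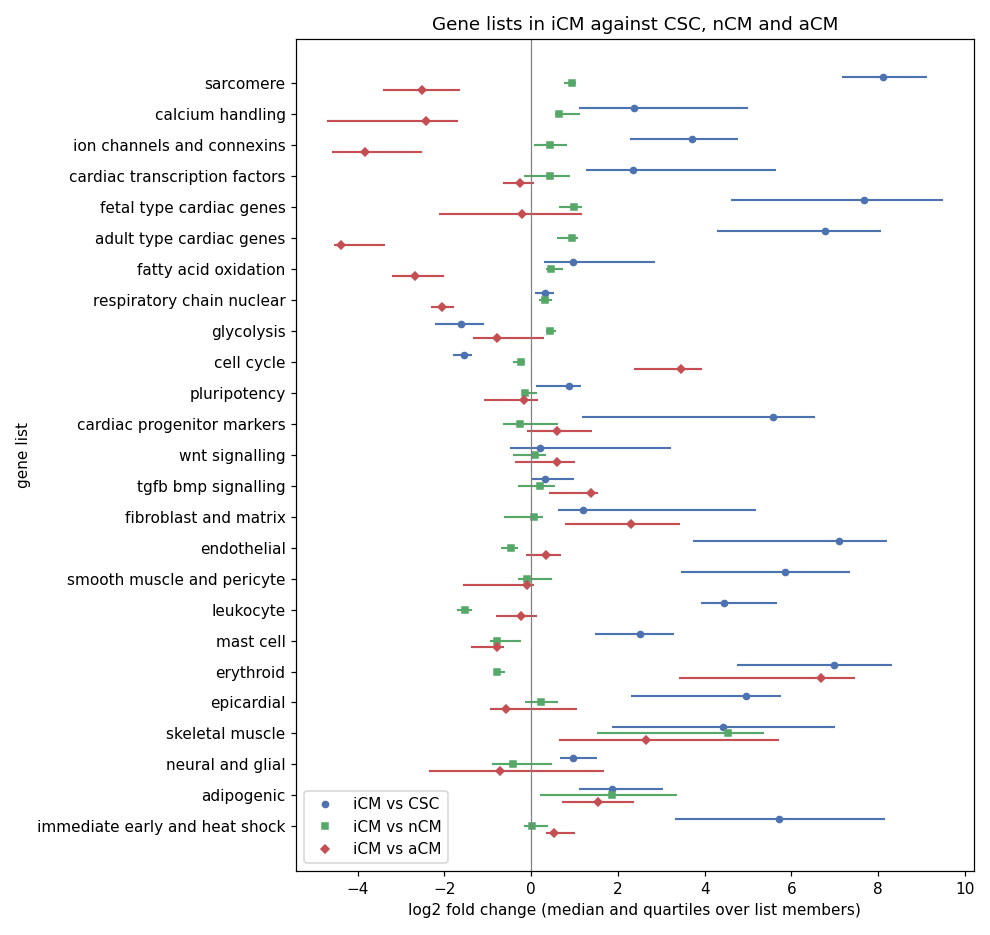
Median log2 fold change of each gene list (points) with the quartiles over its members (lines), for iCM against CSC (blue circles), nCM (green squares) and aCM (red diamonds). The sarcomere list lies at 8.11, 0.94 and -2.52 and the cell cycle list at -1.56, -0.24 and 3.46, and the medians against aCM of the cardiac transcription factor, fetal-type, pluripotency, smooth muscle and leukocyte lists, and against nCM of the immediate early list, change sign between scalings.

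Between CSC and nCM, 7747 genes passed with at least a 2-fold difference, and 6780 of them (87.5%) also passed between CSC and iCM in the same direction, against 68 in the opposite direction. For a typical gene, iCM covered 0.824 of the log2 difference between CSC and nCM (median, with quartiles of 0.620 and 0.982). Of 9685 such genes between CSC and aCM, 7329 (75.7%) passed in the same direction and 231 in the opposite one, and the median share was 0.545 (quartiles 0.294 and 0.854). These pairs of comparisons share the CSC libraries. Across genes, which are not independent replicates, the fold changes of iCM and nCM against CSC had a Pearson correlation of 0.926, against 0.510 in 10 simulations of unchanged groups, and a covariance of 3.80 against 0.041, a difference of 3.76. Both comparisons called 5050 genes higher and 4823 lower, where independent lists would share 2201 and 1905. The simulations shared 0, which unchanged groups give by construction, so that is no chance level for the shared calls. For aCM the correlation was 0.813 against 0.470, the covariance difference 3.88, and the shared calls 4794 higher and 4350 lower, against 2593 and 1868. With 3 CSC libraries no division of the controls leaves 2 in each part, and none was made, so part of the excess may come from the shared libraries.

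In distance, iCM lay closest to nCM. Distances, like the shares above, take each library as a whole and cannot tell cell makeup from the state of the cardiomyocytes. The root mean square log2 difference between iCM and nCM libraries averaged 0.820 over 9 pairs, against 1.45 between iCM and aCM, 1.99 between iCM and CSC and 1.53 between nCM and aCM. CSC lay at 2.14 from nCM and 2.50 from aCM. Within groups it was 0.630 in CSC, 0.386 in iCM, 0.427 in nCM and 0.520 in aCM. The mean Spearman correlation across genes was 0.965 for iCM and nCM, 0.888 for iCM and aCM and 0.848 for iCM and CSC. Each pair of groups gave p = 0.1 in a 1-sided exact permutation test of between-group minus within-group distance, the smallest value that 3 against 3 libraries allow.

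**Figure D3:**
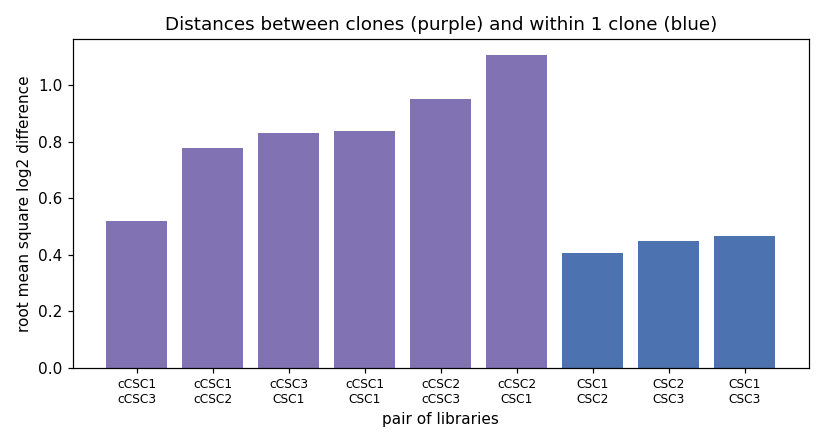
Root mean square log2 difference between pairs of CSC libraries, with bars for pairs of different clones (purple) and for pairs of cultures of 1 clone (blue). Pairs of clones lie between 0.518 and 1.11 and pairs of cultures between 0.407 and 0.466.

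The clone libraries address how alike separate CSC clones are, with 1 library per clone and so no replicate check. The most similar pair of clones was cCSC1 and cCSC3, at a distance of 0.518, and the least similar was cCSC2 and CSC replicate 1, at 1.11. The mean over 6 pairs of clones was 0.837, against 0.441 over 3 pairs of cultures of the same clone, a ratio of 1.9. The columns for cCSC1 and cCSC2 hold few whole numbers, so these 2 may have been made differently from the others, while cCSC3, deposited as estimated counts, lay 0.830 from CSC replicate 1. Over 12187 genes, 77 to 778 genes stood at least 4-fold apart between clones, against 62 to 86 between cultures. In cCSC1, cCSC2 and cCSC3, 53 genes were at least 16-fold higher than in any culture of clone 4, and 0 were as much lower. Genes with large ranges included Gabrb1, a GABA receptor subunit, at 3350, 2860 and 1660 CPM in cCSC1, cCSC2 and cCSC3 against 0.199 in CSC replicate 1, the glutamate transporter Slc1a1 (1700, 1600 and 1520 against 1.28), Lgi3 (1110, 1030 and 922 against 1.63) and thrombospondin 2 (Thbs2), high in cCSC2 alone (8.14, 3980 and 0.804 against 6.30). The fibroblast and matrix list averaged 8.65 (log2) in cCSC2 and 6.26 to 6.67 in the other clones, and the respiratory chain list 6.89 to 7.34 over the clones.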

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

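Alternatives chosen after seeing the data were the authors' library factors, total count scaling, iCM replicate 1 alone, CSC replicate 3 alone, and prior counts of 0.5 and 10. The cause of each change was not tested, except where fewer libraries or a stricter rule leaves fewer genes by construction. Over 4 scalings of the same counts, the shifts of the median of all genes beyond 0.1 on the log2 scale were 0.287 for aCM against CSC in the chosen scaling and 0.133 with RLE, and with total count scaling 0.181 for iCM against CSC, 0.280 for iCM against aCM, -0.354 for aCM against nCM, 0.256 for nCM against CSC and 0.111 for aCM against CSC. With the chosen scaling, other low-count filters and leaving libraries out gave 0.117 to 0.36 for aCM against CSC, up to 0.156 for nCM against CSC and up to 0.133 for iCM against CSC. Of 150 list medians, 10 changed sign over 4 scalings, the 6 named with the list plot and those of pluripotency and adipogenic genes for aCM against nCM, the respiratory chain for nCM against CSC and Wnt signalling for aCM against CSC (-0.16 to 0.06). Genes under about 3 counts could not be compared at this depth.

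Leaving out 1 replicate gave 3494 to 5079 genes for iCM against nCM, 1231 to 2075 of them lower. With iCM replicate 1 alone, whose spread is assumed to be like that of the other groups, it was 1059 (918 higher, 141 lower), of which 1043 were among the 5412. A change of at least 2-fold left 6553 genes for iCM against CSC (2184 lower), 1866 for iCM against nCM (1006 higher, 860 lower), 6194 for iCM against aCM (2952 and 3242), 6295 for aCM against nCM (3249 and 3046), 7747 for nCM against CSC (2949 lower) and, for aCM against CSC, 3820 lower. With an estimated correlation 0 lists passed in each comparison, in place of 19 (iCM against CSC), 12 (iCM against nCM), 11 (iCM against aCM), 14 (aCM against nCM), 17 (nCM against CSC) and 17 (aCM against CSC). In the same order fry gave 24, 10, 20, 21, 22 and 22, and for iCM against nCM it lost the respiratory chain (adjusted p = 0.109), cell cycle (adjusted p = 0.357) and endothelial (adjusted p = 0.0639) lists.

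With a prior count of 0.5, distances were 2.09 (iCM and CSC), 1.51 (iCM and aCM), 1.58 (aCM and nCM), 2.25 (nCM and CSC) and 2.61 (aCM and CSC), and with 10 they were 1.76, 1.34, 1.42, 1.89 and 2.26, and 0.73 for iCM and nCM. The stricter low-count filter gave 2.18, 1.51, 1.62, 2.32 and 2.76. Among clones, a pseudocount of 0.1 gave 1.04 between clones and 0.57 within 1 clone, a pseudocount of 5 gave 0.62 and 0.32, and the stricter filter gave 0.40 within 1 clone. Pseudocounts planned for normalized values were not run for the counts.

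Genes that changed direction had not passed. Log2 values were, for Acsl1 (iCM against CSC), -0.07 with RLE and with DESeq2, -0.09 with the authors' factors and -0.05 with CSC replicate 3 alone, and for Eno3 -0.03 with RLE and with DESeq2, -0.05 with the authors' factors, -0.04 with iCM replicate 1 alone and -0.29 to 1.44 leaving out 1 replicate, and 1.41 with CSC replicate 3 alone. For Cd14 they were 0.05 with total counts, 0.04 with the stricter filter, 0.36 with CSC replicate 3 alone and -0.22 to 0.17 leaving out 1, for Fn1 -0.11 to 0.58 leaving out 1, and for Myc 0.10 with total counts, 0.09 with the stricter filter, 0.01 with the replicate block, 0.00 with CSC replicate 3 alone and -0.10 to 0.10 leaving out 1. For iCM against aCM, Lyz2 gave -0.06 to 0.54 leaving out 1. For aCM against nCM, Myl4 gave 0.01 with the stricter filter and -0.44 to 0.55 leaving out 1, Cd36 -0.22 with total counts and -0.11 to 0.28 leaving out 1, and Kit -0.08 with total counts. Ahsp (nCM against CSC) gave 0.09 with total counts, 0.08 with the stricter filter and -0.48 to 0.18 leaving out 1. Hba2 (aCM against CSC) gave -0.04 with RLE and with total counts, -0.11 with the authors' factors and -0.48 to 7.95 leaving out 1, where the highest value rests on CSC counts of 2 and 3 and is no exact fold.

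Libraries with the same replicate number did not pair. Over 18 such pairs the correlation of deviations was -0.20 to 0.07, 0 were over 0.1, and 0 of 12 libraries correlated best with their own number. With the replicate block, 4719 genes passed for iCM against nCM (2832 higher, 1887 lower).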

Other observations

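All tests in this part were chosen after the result was seen, except the count of glucocorticoid-responsive genes, whose bound was set beforehand.

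Several genes stood in iCM above every other group. In iCM, 242 genes were at least 2-fold higher than in CSC, nCM and aCM each. Ces1d, a carboxylesterase, was at 1580, 1320 and 1200 CPM in the iCM libraries and between 70.8 and 140 CPM in aCM. Gsta1, a glutathione transferase, was at 324, 337 and 317 CPM in iCM and at most 24.2 CPM elsewhere. The fat cell genes Adipoq (8.61, 5.18 and 6.08 CPM) and Plin1 (3.06, 2.33 and 2.18 CPM) were higher in each iCM library than in any other library. Skeletal muscle genes separated iCM replicates 2 and 3 from iCM replicate 1, with Mylpf at 8.64, 99.6 and 155 CPM and Tnni2 at 0.596, 26.6 and 36.8 CPM.

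For each of the 6 comparisons, the 6 libraries can be parted into 2 groups of 3 in 10 ways, and 1 of the 10, the real grouping itself, gave as many genes as were reported. The real counts were 11374, 5412, 10888, 10815, 12436 and 13445 and the highest of the other splits gave 0 in each. With 10 splits the share cannot fall under 0.05.

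Blood, endothelial and leukocyte transcripts stood in iCM beside those of heart muscle. The 242 genes above all other groups argue against a mixture of unaltered RNA of CSC, nCM and aCM cells as the whole account. They cannot exclude heart cells that were mixed in and changed in culture. Another 29 genes were above 100 CPM in CSC and under 1/20 of that in nCM and aCM. In iCM they stood at a median of 5.57% of the CSC level (quartiles 2.67% and 23.4%). The median iCM to nCM ratio of erythroid markers, 0.581, is far above what carry-over of reads between libraries would leave. The ratio was 0.346 for leukocyte, 0.730 for endothelial and 1.92 for sarcomere genes. It was 0.936 for smooth muscle and pericyte, 1.05 for fibroblast and matrix and 1.02 for immediate early and heat shock genes. Within the erythroid list the upper quartile of the ratio was 1.16 times the lower, so heart cells of another makeup than nCM in the cultures may contribute and stay open as an explanation. Differentiation of CSC into several cell types, as the design names it, also stays open and was not tested.

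Among the CSC cultures, cardiomyocyte transcripts such as Myh6 were highest in CSC replicate 1 and the globin Hba2 in CSC replicate 2, and both also stood in the clones cCSC1 and cCSC2 (Myh6 at 12.2 and 14.3 CPM, Hba2 at 5.65 and 7.59 CPM). Over 33 genes high in aCM, CSC replicate 1 held a median of 0.0482% of the aCM level (quartiles 0.0387% and 0.0684%), against 0.0171% in CSC replicate 2. Over 9 genes high in nCM, CSC replicate 2 held 0.287% of the nCM level (quartiles 0.243% and 0.295%), against 0% in CSC replicate 1. These 9 genes include the globin genes Hba2, HBB, Hba-a2, Hbb-b1 and Hbb, which may share reads. Such even shares are what carry-over of RNA or reads at that size would give, and it is a candidate explanation for these 2 libraries. For CSC replicate 2, an even share over globin genes cannot tell carry-over from a trace of red blood cells, which would give it too. Carry-over into the clones and a few differentiated cells in the cultures were not tested.

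Kit was low in CSC, although the study's title names it for these cells. Depth argues against being the cause, since the iCM level would have given at least 608 counts in each CSC library. Reads lost in counting are argued against by at least 597 Kit counts in every library of the other groups, and scaling by a log2 difference of at least 5.30 between iCM and CSC over 4 scalings. What keeps Kit low in CSC stays open.

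Fkbp5, Tsc22d3 and Glul, which glucocorticoids induce, were at 492, 737 and 1260 CPM in iCM, against 25.5, 109 and 205 in nCM, 173, 128 and 297 in CSC and 46.1, 161 and 248 in aCM, and a glucocorticoid response in the iCM cultures was put forward as a hypothesis. Of 18 further glucocorticoid-responsive genes, 8 (44.4%) were higher in iCM than in both CSC and nCM. Over all genes tested it was 6.79% (1-sided exact Fisher test, p = 1.05e-05). That test takes genes as independent, which they are not, so its p-value does not measure spread between libraries. Of the 8 genes, 6 had a higher mean in aCM than in iCM, such as Usp2 (141 against 18.3 CPM). Mt2A and Bcl6 were lower in iCM than in CSC (log2 -1.11 and -0.75). The bound set beforehand was a larger share of the list than that and was missed, so the hypothesis may hold in part and stays undecided.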
